A study of Mus musculus with 21 samples.

How the data were processed

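Bulk RNA-seq was measured in mouse bone marrow-derived macrophages, grown for 6 days with 20 ng/ml M-CSF and plated at 1000000 cells, and in apoptotic thymocytes. The libraries fall into 5 groups from the labels: wild-type macrophages without prey (WT_NS) or fed apoptotic thymocytes for 16 h (WT_AT), knockout macrophages without prey (KO_NS) or fed (KO_AT), with 4 libraries each, and thymocytes alone (AT_only) with 3. The labels state that thymocytes were treated with 1 mM staurosporine, an apoptosis-inducing kinase inhibitor, for 3 h; this dose is unusually high and its unit was not verified. They give the bulk genotype as WT or KO without naming the gene. Single-cell RNA-seq was measured in myeloid cells from subcutaneous tumours of the Lewis lung carcinoma line LLC1, taken 14 days after injection of 100000 cells, with 1 library from Rubcn+/- and 1 from Rubcn-/- mice. The deposited name of the first says wild type while its label and cell names say heterozygous, and it was read as Rubcn+/-.

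The bulk table holds counts of reads per gene, made by the authors with featureCounts 1.5.1 on reverse-stranded reads and the GENCODE vM15 annotation of GRCm38, per the file headers. Reads that map to several places or overlap several genes were not counted, per the file headers, so genes of near-identical families (H2-Q, Gbp, Ifi204, Oas, Trbv, Saa3, histones) are uncertain. The aligners STAR 2.5.3a and BWA and the build mm10 are named in the submitters' processing notes. The single-cell files hold deposited UMI counts per cell and gene from Cell Ranger 1.3.1 on mm10, per the labels, and only barcodes kept by the submitters. The reference annotation used here for symbols is a later release than that of the files. Of the 52550 gene identifiers in the bulk table, 52403 matched a symbol, and of the 27998 in the single-cell files, 27645 did. Coordinates are those of the bulk file, on GRCm38.

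Counts of the 16 macrophage libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM scaling, genes kept by filterByExpr and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The contrasts were fed against unfed within each genotype, KO against WT within each feeding state, and the interaction, which is the feeding effect in KO minus that in WT. AT_only was compared with WT_NS in a separate fit. CPM values use TMM scaling over all 19 bulk libraries. The common dispersion corresponded to a coefficient of variation of 3.57% between replicates. A gene at 0 counts in a group is given a fold bound from a floor of 3 counts over that group, and with 1 to 3 counts the ratio is given with its exact 95% interval. Intervals and floors cover counting error only.

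The 22 gene lists, cell markers included, were tested in each macrophage contrast with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a contrast and at least 3 tested members. The lists are LC3-associated phagocytosis (LAP) and autophagy machinery, type I interferon response, interferon-gamma and MHC genes, pro-inflammatory genes, alternative activation, efferocytosis, LXR and PPAR targets with lipid handling, cholesterol biosynthesis, lysosome, nucleic acid sensing, oxidative stress, glycolysis and hypoxia, cell cycle, integrated stress and unfolded protein response, and markers of thymocytes and T cells, macrophages, monocytes, neutrophils, dendritic cells, B cells, stromal cells and erythroid cells. Lists, groups, tests, the rule for named genes and most alternatives were fixed before the data were examined. For each contrast the named genes are Rubcn, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, and, in each list that passed, the 3 members with the smallest p in the direction of the test. Among the largest rises and falls, predicted genes were left out, as were, for contrasts with a fed group, genes whose AT_only mean reached 50% of that of the higher group. List members were named without these limits, so some, such as Slc7a11, Tcf7 and Thy1, are abundant in prey. For AT_only against WT_NS it is 5 each way without the prey limit. For the interaction, no overlap was taken to mean that every KO_AT library's log2(CPM + 1) minus the KO_NS mean lay on the same side of every WT_AT library's value minus the WT_NS mean.

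The share of prey RNA in a fed library is the median, over thymocyte markers, of the rise above unfed macrophages of the same genotype divided by the AT_only level. Genotypes were compared by an exact 2-sided permutation test.

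Single cells with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs were kept. Scrublet marked doublets per library. Both libraries were clustered together with scanpy 1.11.5 and the Leiden method of igraph 0.11.9 (2000 variable genes, 30 components, 15 neighbours, resolution 1). A cluster was named after the class, from markers fixed beforehand, that had both the highest mean rise over the other clusters and the most markers raised 2-fold, where these were at least 5 and no other class had more markers among the 10 leading genes. That naming rule was chosen after the clusters were seen. UMIs were summed per class and library, and list ratios used members with at least 20 UMIs. Each list's median was set against 10000 random lists matched on expression. With 1 library per genotype there is no test. Named single-cell genes have at least 50 UMIs, at least a 2-fold ratio and exact 95% Poisson intervals that do not overlap, with the 6 largest ratios each way.

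The scripts were tested on simulated counts with 200 changed genes, all drawn from those above the median level. In the comparison of KO_NS with WT_NS, 58% of genes changed 1.1-fold and 100% of those changed 1.25-fold were recovered among 18360, with 13 unchanged genes called. For the interaction the recovered shares were 16% and 84%, with 16 unchanged genes called. With the lysosome list alone shifted 1.2-fold in simulated KO_NS libraries, that list and 2 others of 22 tested were called, nucleic acid sensing and macrophage markers. Those 2 share 1 and 2 genes with it and did not pass without them (adjusted p = 0.458 and 0.957), so lists with shared genes are not independent. Alternatives covered scaling, DESeq2 1.42.0, limma-voom, the filter, the libraries in the fit, a replicate block, each replicate left out, a minimum fold, genes higher in prey left out, camera with an estimated correlation, fry, and filters and clustering of the single cells.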

Results

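Macrophage transcriptomes were measured in 16 bulk libraries and thymocyte transcriptomes in 3. Total counts per library ran from 58165021 to 79817849 in WT_NS, from 39548153 to 58580935 in WT_AT, from 50070027 to 98123095 in KO_NS, from 54957717 to 84368262 in KO_AT and from 16666634 to 30448009 in AT_only. The single-cell libraries held 3213 barcodes from Rubcn+/- and 1624 from Rubcn-/- tumours, with median depths of 7177 and 8295.5 UMIs. Nothing in the labels says whether replicates are separate cultures or animals, so p-values measure only the spread between these samples. Rubcn encodes Rubicon, a protein required for LC3-associated phagocytosis, in which phagosomes are decorated with LC3.

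Rubcn (ENSMUSG00000035629.17; GRCm38 chromosome 16, 32821703 to 32877766) was detected in every library, and lower in KO than in WT in both feeding states. Its level was 73.3 ± 3.02 CPM in WT_NS, 50.3 ± 1.3 in KO_NS, 56.6 ± 1.62 in WT_AT and 43.6 ± 1.31 in KO_AT (mean ± SD, n = 4). The libraries ran from 69.3 to 76.3 CPM in WT_NS, from 49.4 to 52.2 in KO_NS, from 55.3 to 58.9 in WT_AT, from 42.0 to 45.1 in KO_AT and from 27.2 to 28.0 in AT_only, so no KO library overlapped the WT libraries of its feeding state. The KO level was 68.6% of WT without prey and 77.2% with prey. Log2 fold changes were -0.54 (SE 0.032, adjusted p = 3.8e-12) and -0.38 (SE 0.033, adjusted p = 1.12e-08). Counts per gene do not show which exons were read.

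**Figure D1:**
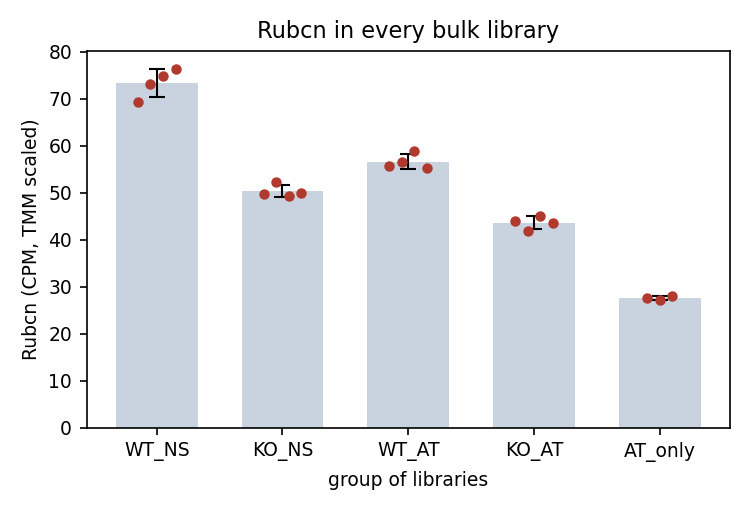
Rubcn in CPM (vertical axis) for each group of bulk libraries (horizontal axis); bars are means, error bars are SD and points are libraries. KO_NS libraries lie between 49.4 and 52.2 CPM, below all WT_NS libraries, which lie between 69.3 and 76.3 CPM.

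The first comparison asks how wild-type macrophages respond to apoptotic cells. Only fed macrophages met staurosporine-treated thymocytes, and no macrophage group received the drug without prey or untreated prey. Effects of the prey and of any drug carried with it therefore cannot be told apart in either genotype. Feeding raised Thbs1 and Il1b and lowered Cx3cr1, Plau and all 40 cell cycle genes. Thbs1, a matrix glycoprotein (ENSMUSG00000040152.8; chromosome 2, 118111876 to 118127133), rose from 89.0 ± 10.9 to 11600 ± 563 CPM, 129.6-fold. Il1b, a pro-inflammatory cytokine (ENSMUSG00000027398.13; chromosome 2, 129364570 to 129371139), rose from 0.825 ± 0.115 to 106.6 ± 5.21 CPM. Cx3cr1, the fractalkine receptor, fell from 202.8 ± 4.42 to 4.68 ± 0.624 CPM, and Plau, the urokinase-type plasminogen activator, fell from 1163 ± 36.7 to 32.7 ± 2.54 CPM.

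The largest log2 rises in WT were those of Cxcl3 at 7.62 (SE 0.191, adjusted p = 4.64e-21), Trem1 at 7.51, Il1b and Thbs1 at 7.02, Mcemp1 at 6.88 and Vcan at 6.18. The largest falls were Cx3cr1 at -5.45 (SE 0.057, adjusted p = 3.54e-28), Efr3b at -5.40, Tox2 at -5.33, Plau at -5.16, Ptchd1 at -5.14 and Ccnd1, which encodes cyclin D1, at -4.72. In all, 6153 genes were higher and 6488 lower in fed WT among 18360 tested, 3225 of them changed at least 2-fold. Of pro-inflammatory genes, 29 rose and 8 fell of 41 (adjusted p = 1.49e-11), among them Cxcl2 at 5.88 and Tnfaip2 at 1.82 on the log2 scale. Cell cycle genes fell by a median of 2.03 on the log2 scale (adjusted p = 5.81e-62), with Pcna at -2.73, Mcm6 at -2.68 and Mcm5 at -2.97, although 36 of the 40 were higher in AT_only than in WT_NS. Of 15 neutrophil markers 11 rose and 1 fell (adjusted p = 1.97e-07), including Clec4d at 2.63 and Mmp8 at 2.78. Monocyte markers rose in 12 and fell in 2 of 15 (adjusted p = 5.57e-05), with F13a1 at 1.53. Markers of thymocytes rose in 39 of 39 (adjusted p = 3.62e-35), with Tcf7 at 7.93, Lck at 5.63 and Rag1 at 9.89. AT_only exceeded WT_NS for all 39 T cell, 9 neutrophil and 7 monocyte markers. These 5 calls also held with an estimated correlation.

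Another 6 lists passed in WT only at the preset correlation. Oxidative stress genes rose in 22 and fell in 7 of 30 (adjusted p = 2.79e-07, and adjusted p = 0.184 with an estimated correlation), with Slc7a11, a cystine transporter, at 4.13, Nqo1 at 2.71 and Sod2 at 1.35. Cholesterol biosynthesis genes fell in 19 and rose in 4 of 26 (adjusted p = 0.000379, and adjusted p = 0.321 with an estimated correlation), with the enzymes Cyp51 at -0.98, Sqle at -0.92 and Sc5d at -0.66. Stress response genes fell in 20 and rose in 7 of 28 (adjusted p = 0.000896, and adjusted p = 0.31 with an estimated correlation), with Atf3 at -1.77, Psat1 at -2.09 and Asns at -2.21. Macrophage markers rose in 18 and fell in 8 of 30 (adjusted p = 0.00344, and adjusted p = 0.42 with an estimated correlation), with Cd14 at 2.23, Clec4n at 3.64 and Mrc1 at 2.08. LAP and autophagy genes rose in 20 and fell in 7 of 37 (adjusted p = 0.0142, and adjusted p = 0.471 with an estimated correlation); Uvrag rose by 1.29, and Ncf1, a subunit of the phagocyte NADPH oxidase, by 0.63. Stromal markers rose in 16 and fell in 3 of 20 (adjusted p = 0.0142, and adjusted p = 0.677 with an estimated correlation), with Thy1, also a thymocyte gene, at 4.96, Dcn at 3.51 and Col3a1 at 2.12. Without genes higher in AT_only, adjusted p became 0.153 for the stress response and 0.0771 for stromal markers. The counts of these 11 lists were the same when adjusted over the list alone.

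The remaining lists did not pass in fed WT. Members higher and lower numbered 20 and 13 of 49 for type I interferon (adjusted p = 0.418), 18 and 11 of 39 for interferon-gamma and MHC (0.283), 18 and 12 of 33 for alternative activation (0.453), 13 and 19 of 35 for LXR and PPAR targets (0.101), 20 and 23 of 50 for lysosome (0.129), 14 and 9 of 28 for nucleic acid sensing (0.262) and 7 and 16 of 25 for glycolysis and hypoxia (0.575). They numbered 9 and 8 of 22 for dendritic cell (0.453), 7 and 0 of 8 for B cell (0.0994) and 1 and 0 of 3 for erythroid markers (0.774). Without WT_AT replicate 4 the B cell list passed at adjusted p = 0.0453. Efferocytosis genes numbered 16 higher and 17 lower of 38 (0.799), with a median of -0.04 and a mean of 0.10 on the log2 scale and a test directed down. Adjusted over the list alone, 12 interferon-gamma and MHC genes were lower and 19 alternative activation genes higher, and the other counts were unchanged.

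Knockout macrophages were compared in the same way to ask whether they respond to apoptotic cells. Feeding raised Il6, a pro-inflammatory cytokine (ENSMUSG00000025746.11; chromosome 5, 30013114 to 30019981), from 1 count over all KO_NS libraries to 1501 counts, a ratio of 1584 (exact 95% interval 283.8 to 62590). Il1b rose from 1.99 ± 0.167 to 209.4 ± 20.4 CPM and Thbs1 from 95.8 ± 14.7 to 10940 ± 487 CPM. Plau fell from 1242 ± 42.0 to 33.9 ± 1.64 CPM.

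Besides Il6, the largest log2 rises in KO were Cxcl3 at 8.38 (SE 0.203, adjusted p = 2.5e-21), Trem1 at 7.74, Ereg, an epidermal growth factor family ligand, at 6.88, Thbs1 at 6.82 and Il1b at 6.72. Falls were largest for Tox2 at -6.17 (SE 0.111, adjusted p = 9.67e-24), Plau at -5.21, Efr3b at -5.16, Ptchd1 at -5.15, Ccnd1 at -4.89 and Sncaip at -4.87. In all, 6153 genes were higher and 6469 lower, 3074 of them by at least 2-fold. Across genes, which are not independent replicates, the feeding effects in WT and KO had Pearson r = 0.950 and a Spearman correlation of 0.907. Higher in both were 5407 genes, where independent lists would share 2062.1, and lower in both were 5654, where independent lists would share 2286. Cell cycle genes fell in 40 of 40 (adjusted p = 8.78e-78), pro-inflammatory genes rose in 30 and fell in 7 of 41 (adjusted p = 9.44e-10), neutrophil markers rose in 9 and fell in 1 of 15 (adjusted p = 2.25e-07) and T cell markers rose in 39 of 39 (adjusted p = 5.39e-37). These 4 calls held with an estimated correlation.

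A further 8 lists passed in KO only at the preset correlation. Oxidative stress genes rose in 23 and fell in 5 of 30 (adjusted p = 1.86e-10, and adjusted p = 0.0747 with an estimated correlation), with Slc7a11 at 4.55, Nqo1 at 2.81 and Sod2 at 1.77. Monocyte markers rose in 11 and fell in 2 of 15 (adjusted p = 0.000107, and adjusted p = 0.0747 with an estimated correlation), among them Vcan at 6.36. Stress response genes fell in 20 and rose in 7 of 28 (adjusted p = 0.00086, and adjusted p = 0.258 with an estimated correlation). Stromal markers rose in 16 and fell in 1 of 20 (adjusted p = 0.00125, and adjusted p = 0.57 with an estimated correlation), with Fstl1 at 2.23. Cholesterol genes fell in 18 and rose in 3 of 26 (adjusted p = 0.00217, and adjusted p = 0.386 with an estimated correlation). LAP and autophagy genes rose in 23 and fell in 9 of 37 (adjusted p = 0.0159, and adjusted p = 0.54 with an estimated correlation), with Ncf4 at 0.82. Macrophage markers rose in 17 and fell in 9 of 30 (adjusted p = 0.0179, and adjusted p = 0.57 with an estimated correlation), with Fcgr3 at 1.02. Lysosome genes fell in 24 and rose in 18 of 50 (adjusted p = 0.0308, and adjusted p = 0.749 with an estimated correlation), with Atp6v0a1, a proton pump subunit, at -1.46 and Lipa at -1.39. Without genes higher in AT_only, adjusted p became 0.193 for lysosome and 0.0677 for the stress response. Adjusted over the list alone, 10 LAP and autophagy genes fell, and the counts of the other passing lists were the same.

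Prey RNA accompanied both fed groups. Its share was 3.22% ± 0.366 of the AT_only level in WT_AT and 3.10% ± 0.0463 in KO_AT (SD, n = 4), a difference of -0.12 percentage points (exact 2-sided permutation test, p = 0.657). Leaving out WT_AT replicate 2 gave a difference of -0.30 (exact 2-sided permutation test, p = 0.0286), the smallest p that 35 splits allow. At the highest share among the 32 thymocyte markers with at least 50 CPM in AT_only, 6.36% in WT and 6.60% in KO, prey RNA could cover the rise of 878 of the 6153 genes higher in fed WT (14.3%) and 864 of the 6153 in fed KO (14.0%). Markers less abundant in AT_only had shares of up to 63.8% in WT, which were not used.

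Thymocytes alone, beside WT_NS, carried the T cell genes Rag1, a recombinase of lymphocyte receptor genes, at 16.9 log2 higher, and Nsg2, at least 7261-fold higher. Trbv15 and Trbv12-2, T cell receptor segments counted from uniquely mapped reads, were at least 5057-fold and at least 4398-fold higher. Cd8b1, a T cell coreceptor chain, had 2 counts in WT_NS and a ratio of 25970 (exact 95% interval 7188 to 214400). Gdf3, Cxcl14, Tmem273 and Eya4 had 0 counts in AT_only and were at least 2789-fold, at least 2071-fold, at least 1173-fold and at least 747.9-fold lower. Pcp4l1 had 1 count in AT_only and was lower by a ratio of 14140 (exact 95% interval 2538 to 558600). In all, 8112 genes were higher and 8432 lower of 18788.

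Genotype was compared first without prey, to ask what the knockout changes in resting macrophages. KO_NS macrophages expressed more Ccl2 and Ccl7, which attract monocytes, more of the MHC class II genes H2-Eb1 and H2-Ab1, and more of their transactivator Ciita. Ccl2 (ENSMUSG00000035385.5; chromosome 11, 82035571 to 82037453) was at 31.0 ± 3.57 CPM in KO_NS and 10.9 ± 1.36 in WT_NS, and H2-Eb1 at 50.1 ± 3.32 and 21.1 ± 0.835 CPM. Rhoj, which encodes a small GTPase (ENSMUSG00000046768.13; chromosome 12, 75308322 to 75401456), was at 1.56 ± 0.120 CPM in KO_NS and 14.2 ± 0.867 in WT_NS. Gdf3, a TGF-beta family ligand, was at 23.5 ± 0.566 and 98.5 ± 1.40 CPM.

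The largest log2 rises in KO_NS were Ccl2 at 1.52 (SE 0.080, adjusted p = 4.4e-13), Ccl7 at 1.48, Ciita at 1.47, Rab4a at 1.44, Gpr162 at 1.40 and Fkbp9 at 1.39. Lower were Rhoj at -3.20 (SE 0.069, adjusted p = 4.17e-20), Lrmda at -2.83, Gdf3 at -2.07, Tmeff1 at -1.71, B3gnt7 at -1.68 and Cd207, a C-type lectin, at -1.66. Of 18360 genes, 2582 were higher and 2625 lower, 276 of them by at least 2-fold. None of the 7 lists that passed held with an estimated correlation. Interferon-gamma and MHC genes were higher in 18 and lower in 0 of 39 (adjusted p = 1.59e-09, and adjusted p = 0.2 with an estimated correlation), with H2-Ab1 at 0.95. Pro-inflammatory genes were higher in 20 and lower in 5 of 41 (adjusted p = 1.05e-07, and adjusted p = 0.168 with an estimated correlation), with Tnfaip2 at 0.50 and the adhesion molecule Icam1 at 0.43. Cell cycle genes were higher in 31 and lower in 2 of 40 (adjusted p = 3.88e-15, and adjusted p = 0.2 with an estimated correlation), with Ccnb2 at 0.50, Kif11 at 0.52 and Top2a at 0.48. Macrophage markers were higher in 16 and lower in 7 of 30 (adjusted p = 0.000975, and adjusted p = 0.445 with an estimated correlation), with Lyz2 at 0.61, Mrc1 at 0.65 and Clec4n at 1.02.

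Cholesterol biosynthesis genes were lower in 20 and higher in 1 of 26 (adjusted p = 4.57e-10, and adjusted p = 0.168 with an estimated correlation), with Cyp51 at -0.33, Hsd17b7 at -0.41 and Sqle at -0.29. Oxidative stress genes were lower in 22 and higher in 3 of 30 (adjusted p = 2.5e-08, and adjusted p = 0.2 with an estimated correlation); Gclm and Gclc, subunits of the enzyme that starts glutathione synthesis, were at -0.66 and -0.36, and Taldo1 at -0.46. Stress response genes were lower in 14 and higher in 13 of 28 (adjusted p = 0.00141, and adjusted p = 0.316 with an estimated correlation), with Asns at -1.01, Mthfd2 at -0.78 and Atf5 at -0.72. Without genes higher in AT_only, adjusted p became 0.44 for both the cell cycle and the stress response, and the stress response test turned upward. That setting took out 36 of the 40 cell cycle and 13 of the 28 stress response genes. Since these groups received no prey, it does not test prey RNA here. Type I interferon genes did not pass, with 11 higher and 5 lower of 49 (adjusted p = 0.442). Of the lists that did not pass, the alternative test fry called neutrophil markers lower (adjusted p = 0.0366). Fry called nucleic acid sensing genes (0.0048) and monocyte (0.00543), dendritic cell (0.00327) and B cell markers (0.0135) higher. Adjusted over the list alone, 3 interferon-gamma and MHC genes and 3 cell cycle genes were lower, 21 pro-inflammatory genes were higher and 8 macrophage markers lower.

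The comparison of genotypes after feeding asks how fed KO and WT macrophages differ, which includes differences already present without prey. Fed KO macrophages expressed more Il1b, Il6 and Marco and more glycolysis genes. Il1b was at 209.4 ± 20.4 CPM in KO_AT and 106.6 ± 5.21 in WT_AT, and Il6 at 5.51 ± 1.18 and 2.37 ± 0.557. Marco, a scavenger receptor (ENSMUSG00000026390.7; chromosome 1, 120474538 to 120505024), was at 8.57 ± 0.638 and 1.88 ± 0.0923 CPM. Marco was already higher without prey, at 1.742 CPM in KO_NS and 0.5324 in WT_NS. So was Il1b, whose log2 rise with feeding was smaller in KO than in WT. Slc16a3, a lactate exporter, was at 219.5 ± 6.71 and 157.2 ± 5.95 CPM. The neutrophil chemokine Cxcl1 was lower, at 4.29 ± 0.351 and 11.9 ± 0.704 CPM.

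The largest log2 rises in KO_AT were Marco at 2.18 (SE 0.101, adjusted p = 1.87e-13), Saa3 at 1.64, the oxygen sensor Egln3 at 1.53, Il6 at 1.23, Fat3 at 1.19 and Speg at 1.16. Lower were Rhoj at -3.11 (SE 0.061, adjusted p = 4.62e-21), Lrmda at -2.74, B3gnt7 at -1.99, Gdf3 at -1.94, Dmpk at -1.66 and Cxcl1 at -1.48. Of 18360 genes, 1415 were higher and 1181 lower, 135 of them by at least 2-fold. Glycolysis and hypoxia genes were higher in 21 and lower in 1 of 25 (adjusted p = 1.71e-37), a call that held with an estimated correlation (adjusted p = 0.00661). Among them were Pfkl at 0.41, Slc16a3 at 0.48 and Tpi1 at 0.38. Cholesterol genes were lower in 15 and higher in 2 of 26 (adjusted p = 5.05e-07, and adjusted p = 0.205 with an estimated correlation), with Cyp51 and Msmo1 at -0.22. Stromal markers were higher in 9 and lower in 0 of 20 (adjusted p = 5.62e-06, and adjusted p = 0.513 with an estimated correlation), with Col1a1 at 1.11, Postn at 1.02 and Col1a2 at 0.80. Cell cycle genes were higher in 21 and lower in 0 of 40 (adjusted p = 1.1e-09, and adjusted p = 0.463 with an estimated correlation), with Top2a at 0.43 and Mki67 and Nusap1 at 0.53. Stress response genes were lower in 10 and higher in 9 of 28 (adjusted p = 0.00266, and adjusted p = 0.463 with an estimated correlation), with Mthfd2 at -0.73, Atf4 at -0.35 and Asns at -0.61.

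Another 5 lists passed between the fed genotypes. Pro-inflammatory genes were higher in 16 and lower in 10 of 41 (adjusted p = 0.00737, and adjusted p = 0.513 with an estimated correlation), with Il1b at 0.97, Acod1, the enzyme that makes itaconate, at 1.07 and Nlrp3 at 0.30. Neutrophil markers were lower in 8 and higher in 2 of 15, with a median of -0.59 (adjusted p = 0.00737, and adjusted p = 0.205 with an estimated correlation), with Trem1 at -0.71, Ngp at -1.73 and Clec4d at -0.18. Type I interferon genes were lower in 13 and higher in 3 of 49 (adjusted p = 0.0245, and adjusted p = 0.834 with an estimated correlation), with Ifi204 at -0.31, Oas3 at -0.57 and Oas2 at -0.41. Oxidative stress genes were lower in 12 and higher in 5 of 30 (adjusted p = 0.0262, and adjusted p = 0.745 with an estimated correlation), with Nqo1 at -0.43, Taldo1 at -0.22 and Gclc at -0.19. Macrophage markers were higher in 11 and lower in 7 of 30 (adjusted p = 0.0431, and adjusted p = 0.745 with an estimated correlation), with Cx3cr1 at 0.97, Cd14 at 0.27 and Lyz2 at 0.24. Without genes higher in AT_only, 3 of the 10 lists passed, and the tests of the stress response (adjusted p = 0.668) and of neutrophil markers (adjusted p = 0.62) turned upward. That setting took out 13 of the 28 stress response genes and 9 of the 15 neutrophil markers. The interferon call ended with fry (adjusted p = 0.248) and without WT_AT replicate 4 (0.306), the pro-inflammatory call without WT_AT replicate 3 (0.0777), the oxidative stress call without WT_AT replicate 2 (0.148) or KO_AT replicate 3 (0.0963), and the macrophage call without WT_AT replicates 1 (0.123) or 3 (0.0777) or KO_AT replicate 1 (0.0994), with a replicate block (0.0516) and with DESeq2 size factors (0.0504). Interferon-gamma and MHC genes, higher in 10 and lower in 6 of 39 (adjusted p = 0.137), passed without WT_AT replicate 4 (adjusted p = 0.0131). Adjusted over the list alone, 16 interferon genes were lower, 22 glycolysis and 19 pro-inflammatory genes higher, 23 cell cycle genes higher and 2 lower, 14 oxidative stress genes lower, 12 macrophage and 10 stromal markers higher.

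**Figure D2:**
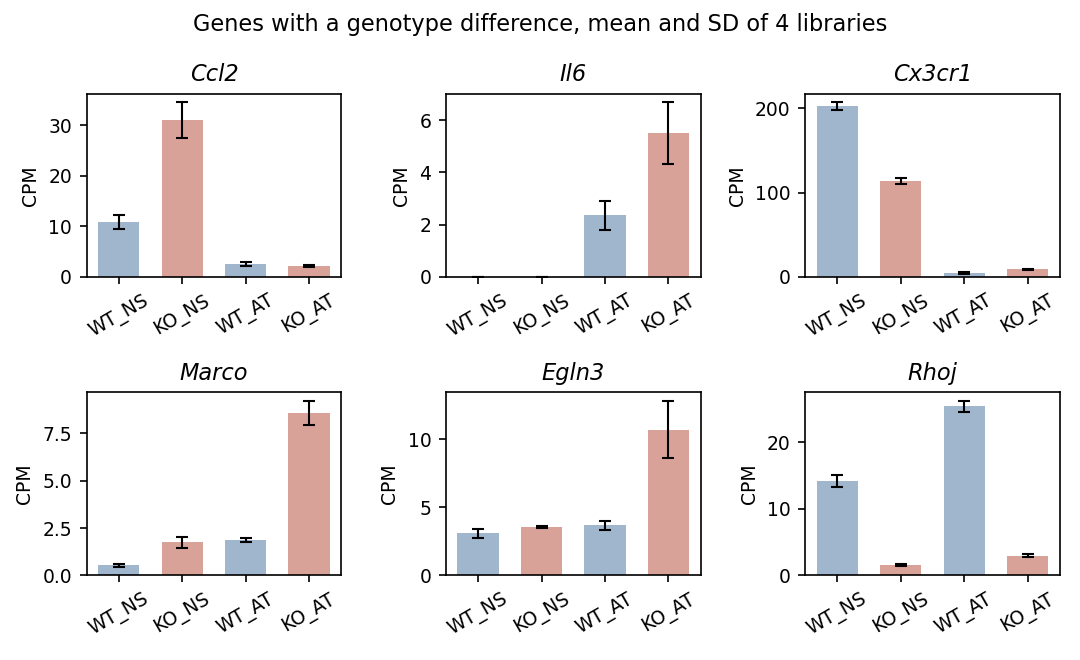
Levels in CPM (vertical axes) of 6 genes by group (horizontal axes); bars are means and error bars SD of 4 libraries. Rhoj has means of 1.56 CPM in KO_NS and 2.96 CPM in KO_AT, and Il6 rises with feeding to 5.51 CPM in KO_AT and 2.37 CPM in WT_AT.

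The interaction asks whether feeding acts differently in the knockout. Feeding lowered Cx3cr1 less in KO, from 113.5 ± 3.55 to 9.11 ± 0.895 CPM, and raised Egln3 from 3.55 ± 0.0922 to 10.7 ± 2.12 CPM in KO beside 3.10 ± 0.334 to 3.68 ± 0.340 CPM in WT. Ccl2 fell from 31.0 to 2.17 ± 0.153 CPM in KO and from 10.9 to 2.48 ± 0.408 CPM in WT. The lectin receptor Mrc1 rose from 185.4 ± 8.15 to 453.8 ± 14.1 CPM in KO and from 119.0 ± 4.08 to 506.1 ± 21.9 CPM in WT.

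Differences of log2 feeding effects, KO minus WT, were largest upward for Cx3cr1 at 1.80 (SE 0.082, adjusted p = 4.54e-13), Tmeff1 at 1.67, Serpinb2 at 1.38, Egln3 at 1.33, Aldh1l2 at 1.298 and Fbln2 at 1.08. They were largest downward for Ccl2 at -1.69 (SE 0.171, adjusted p = 1.8e-07), Ccl7 at -1.65, Mcemp1 at -1.48, Ms4a4a at -1.39, Adgre4 at -1.34 and Ciita at -1.12. Rubcn differed by 0.16 (SE 0.046, adjusted p = 0.0255), and this call ended without WT_NS replicate 4 (adjusted p = 0.0568) or KO_AT replicate 3 (adjusted p = 0.0551). In all, 996 genes had a higher and 1008 a lower difference of 18360. Among the 2004, 548 had a larger effect of the same sign in KO, 1223 a smaller one and 233 effects of opposite sign. Genotype effects without and with prey had Pearson r = 0.446 and a Spearman correlation of 0.322 across genes.

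None of the 11 lists that passed the interaction test held with an estimated correlation. Glycolysis and hypoxia genes had a higher difference in 20 and a lower one in 1 of 25 (adjusted p = 4.88e-21, and adjusted p = 0.0628 with an estimated correlation), with Tpi1 at 0.37, Pfkl at 0.33 and the hexokinase Hk2 at 0.35. Oxidative stress genes were higher in 12 and lower in 1 of 30 (adjusted p = 2.6e-06, and adjusted p = 0.373 with an estimated correlation), with Gclm at 0.48, Sod2 at 0.42 and Txnrd1 at 0.29. Interferon-gamma and MHC genes were lower in 13 and higher in 0 of 39 (adjusted p = 6.5e-08, and adjusted p = 0.335 with an estimated correlation), with Gbp7 at -1.05 and H2-Q4 at -0.41. Pro-inflammatory genes were lower in 14 and higher in 3 of 41 (adjusted p = 7.28e-06, and adjusted p = 0.333 with an estimated correlation), with Tnfaip2 at -0.40. Nucleic acid sensing genes were lower in 6 and higher in 4 of 28 (adjusted p = 0.00298, and adjusted p = 0.448 with an estimated correlation), with the RNA sensor Tlr7 at -0.61, Ikbke at -0.45 and Samhd1 at -0.19. Type I interferon genes were lower in 6 and higher in 0 of 49 (adjusted p = 0.00295, and adjusted p = 0.738 with an estimated correlation), with Ms4a4c at -1.11, Ddx58 at -0.32 and Ddx60 at -0.38; the Ddx60 call ended for 7 libraries left out singly (adjusted p 0.0553 to 0.0739). Macrophage markers were lower in 13 and higher in 6 of 30 (adjusted p = 0.00852, and adjusted p = 0.64 with an estimated correlation), with Mrc1 at -0.81, Maf at -0.45 and Lyz2 at -0.37.

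Another 4 lists passed the interaction test. Cholesterol genes were higher in 6 and lower in 0 of 26 (adjusted p = 0.0163, and adjusted p = 0.64 with an estimated correlation), with Pmvk at 0.27, Sqle at 0.17 and Hsd17b7 at 0.23. Stromal markers were higher in 4 and lower in 0 of 20, with a median of 0.26 (adjusted p = 0.0069, and adjusted p = 0.738 with an estimated correlation), with Fbn1 at 0.77, Acta2 at 0.64 and Tagln at 0.49; the Tagln call ended for 6 libraries left out singly (adjusted p 0.0548 to 0.0915) and with the DESeq2 Wald test (adjusted p = 0.084). Lysosome genes were lower in 10 and higher in 3 of 50 (adjusted p = 0.0196, and adjusted p = 0.778 with an estimated correlation), with Atp6v1b2 at -0.15 and Psap and Npc2 at -0.14. Cell cycle genes were lower in 4 and higher in 2 of 40 (adjusted p = 0.0203, and adjusted p = 0.778 with an estimated correlation), with Ccnb2 at -0.36, Kif23 at -0.31 and Rrm1 at -0.20; without genes higher in AT_only this test turned upward (adjusted p = 0.424), and the calls for cholesterol (0.0965), nucleic acid sensing (0.0636) and stromal genes (0.0636) ended. That setting took out 36 of the 40 cell cycle genes. With fry, a rotation test of lists, the calls for type I interferon (adjusted p = 0.21), lysosome (0.179), cell cycle (0.326) and stromal genes (0.282) ended. Leaving out a single library ended the lysosome call for 6 libraries (adjusted p 0.0571 to 0.171), the cell cycle call for 5 (0.0581 to 0.195), the stromal call for WT_NS replicate 4 (0.0899), WT_AT replicate 2 (0.0558) and KO_AT replicate 2 (0.0521), and the type I interferon call for WT_AT replicate 4 (adjusted p = 0.0524). Adjusted over the list alone, 9 type I interferon, 17 interferon-gamma and MHC, 9 nucleic acid sensing and 12 lysosome genes were lower, and 15 oxidative stress, 7 cholesterol and 5 stromal genes higher.

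Tumour myeloid cells from Rubcn-/- and Rubcn+/- mice were compared to ask how Rubcn affects these cells within a tumour; each genotype is 1 library, so no test applies. Type I interferon genes were higher in monocyte-like cells of the Rubcn-/- library than in those of the Rubcn+/- library. All 48 measured members were higher, with a median ratio of 3.00 over members, or 1.59 on the log2 scale (95% interval over counting error 1.51 to 1.65). Among them Isg15, a ubiquitin-like antiviral protein, was at 2615 and 706.7 CPM, Irf7, a transcription factor of the interferon response, at 1459 and 338.5 CPM, and Ifit3 at 1138 and 189.8 CPM in Rubcn-/- and Rubcn+/-. In macrophage-like cells 40 of 48 members were higher, with a median of 0.41 (0.33 to 0.46), and Isg15 was at 221.3 and 233.4 CPM. Isg15, Irf7 and Ifit3 were picked after their values were seen.

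The monocyte-like class is made of clusters 0 and 4, of which cluster 0 held 691 Rubcn+/- and 135 Rubcn-/- cells and cluster 4, led by interferon genes, 122 and 428. Within clusters 0 and 4 the type I interferon medians were 0.06 and 0.39. Within the monocyte-like clusters formed without interferon and MHC genes the type I interferon medians were -0.09, 0.41 and 0.87, all below that of the whole class; the cluster at 0.41 was still led by Rsad2, Ifit3 and Cxcl10. Type I interferon medians lay above all 10000 random lists in both classes. In dendritic cell 2-like cells 19 members were higher and 23 lower, with a median of -0.08, and when clustered without interferon and MHC genes 44 of 48 were higher over summed UMIs, with a median of 0.70, while the median cell had 0.327% of its UMIs from these genes in Rubcn-/- and 0.443% in Rubcn+/-. Interferon-gamma and MHC genes were higher in 39 of 41 in monocyte-like cells, with a median of 0.76, and lower in 28 of 41 in macrophage-like cells, with a median of -0.23. Nucleic acid sensing genes were higher in 23 of 26 in monocyte-like cells, with a median of 0.77, and pro-inflammatory genes in 28 of 36, with a median of 0.58. In macrophage-like cells cell cycle genes were higher in 40 of 40, with a median of 0.78, and cholesterol genes lower in 21 of 25, with a median of -0.19; this class also joins clusters of unequal make-up, such as cluster 3 with 598 Rubcn+/- and 54 Rubcn-/- cells and cluster 9 with 54 and 160, and these lists were not compared within clusters. Neutrophil markers were lower, with medians of -1.45 in macrophage-like and -2.35 in monocyte-like cells, as were T cell markers at -0.58 and -1.16 and erythroid markers at -3.56 and, with 2 of the 4 members at 0 UMIs, at most -5.05. Stromal markers were higher, at 1.15 over 5 members and 0.96 over 3, and dendritic cell markers were at -0.64 and 0.56, the latter turning negative under other settings. Lysosome genes had medians of 0.14 and 0.24.

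Macrophage-like cells were 53.4% (Clopper-Pearson 95% interval 51.7 to 55.2) of 3195 Rubcn+/- and 43.3% (40.9 to 45.8) of 1590 Rubcn-/- cells, and monocyte-like cells 25.4% (23.9 to 27.0) and 35.4% (33.1 to 37.8); the intervals cover counting error only. With the top 5% of doublet scores removed, macrophage-like shares were 60.6% and 58.9% and monocyte-like shares 22.9% and 25.2%. Clustering without interferon and MHC genes gave 57.3% and 41.5% macrophage-like and 21.3% and 34.9% monocyte-like cells. Scrublet marked 0 and 5 cells, so doublets were not effectively removed. Other classes held 5.38% and 8.81% (dendritic cell 2-like), 4.19% and 3.08% (mature dendritic cell-like) and 11.5% and 9.37% (unnamed).

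By the size rule, the largest ratios in macrophage-like cells were higher in Rubcn-/- for Cst6, Ppbp, Hist1h2ap, Ednrb, Hpgd and Tpm3-rs7, and lower for Gzma, Ccl8, Ccl24, Hbb-bt, Cma1 and Ms4a3. The chemokine Ccl24 was at 165.9 CPM in Rubcn-/- and 2892 in Rubcn+/-, Ccl8 at 12.8 and 270.9, and Ppbp, a platelet chemokine, at 206.1 and 34.8; these genes lead clusters whose shares differ between the libraries. In monocyte-like cells Sct, Aplnr, Apol9b, Ifit3b, Cfb and B4galt4 were higher, with Ifit3b at 264.4 and 23.6 CPM and the complement factor Cfb at 85.4 and 8.10 CPM, and Cd3g, Hba-a2, Ccl24, Hbb-bs, S100a9 and Hba-a1 were lower. Gzma, Cma1, Ms4a3, Cd3g and the haemoglobin genes are transcripts of other cell types, and Cst6, at 49 UMIs in Rubcn-/- and 13 in Rubcn+/-, is among the leading genes of the keratin-expressing cluster 11. S100a9, with 136 UMIs in Rubcn+/- and 5 in Rubcn-/- monocyte-like cells, is on the neutrophil list. No cluster was named neutrophil-like, and which cells carried S100a9 was not tested. Rubcn had 91 UMIs in Rubcn+/- and 30 in Rubcn-/- macrophage-like cells, 5.54 and 4.05 CPM with overlapping intervals, and 16 and 22 UMIs in monocyte-like cells; a 3' tag outside a deletion checks nothing.

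**Figure D3:**
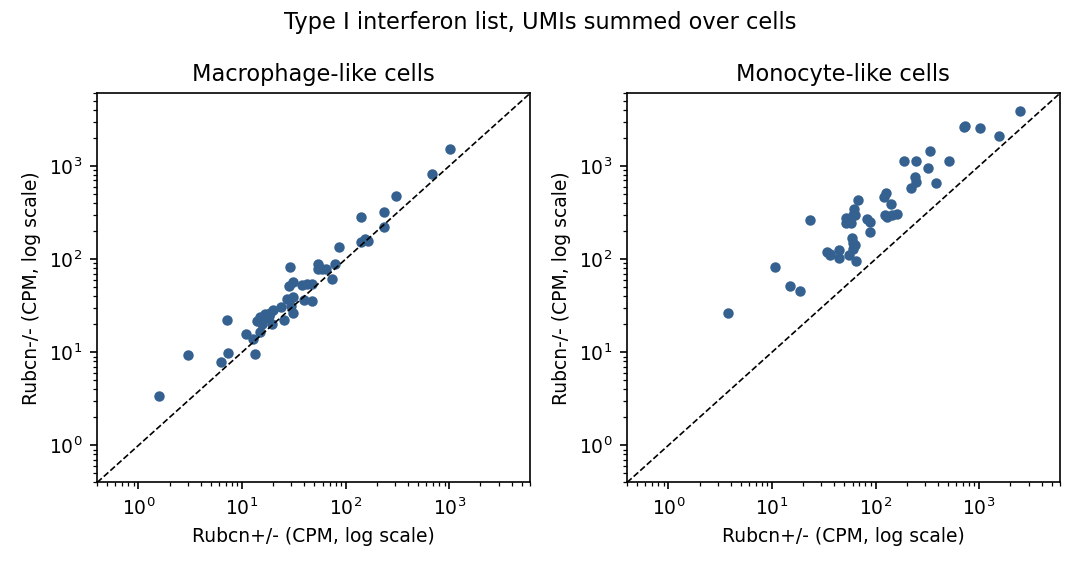
Type I interferon genes in CPM over summed UMIs, Rubcn+/- on the horizontal and Rubcn-/- on the vertical axis, both logarithmic; each point is a gene and the dashed line marks equal levels. In monocyte-like cells all 48 measured members lie above the line, in macrophage-like cells 40 of 48.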

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

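The tests of explanations below were chosen after the results were seen, except that for wild-type macrophages mixed into the KO libraries, and the 3 patterns were weighed against the tables at hand.

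Rubcn counts in the KO libraries stood at 68.61% of WT without prey. Wild-type macrophages as the whole source of these counts would leave no gene below the Rubcn ratio, but 10 of 10120 genes with at least 5 CPM in both WT groups lay below it in both feeding states (1-sided normal test, Bonferroni), with Rhoj at 11% of WT, Lrmda at 14.1% and Gdf3 at 23.8% without prey, which excludes this. Under 50% of WT in both states were 5 genes, fewer than the bound of more than 10 set before, and wild-type macrophages mixed in at a share below the 11% of Rhoj cannot be told apart. Transcripts of a partly deleted gene, counted over the whole gene, could also give this level; counts per exon were not analysed here. A change in the rest of the gene's transcription with genotype stays open and untested.

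Type I interferon genes were higher in the Rubcn-/- tumour library, with a median log2 ratio of 1.413 over all cells. Free RNA as the whole source would raise all clusters alike. Clustered without these genes, the lowest upper bound of the rise was 0.0469 percentage points, in a dendritic cell cluster. The highest lower bound was 0.168, in a macrophage cluster of like depth, which argues against free RNA as the whole source. Both bounds are extremes over clusters with at least 100 cells per library. In summed UMIs, 44 of 48 members were higher in that dendritic cell cluster, with a median of 0.70. An unnamed cluster led by haemoglobin genes, with 64 Rubcn+/- and 20 Rubcn-/- cells, had 34 of 34 members higher. Its median was 1.85 and its rise 0.125 points. A part from free RNA therefore stays open. Different shares of macrophage-like clusters as the whole source would leave no rise within them, but medians were 0.86 and 0.67 in clusters 6 and 1; they were 0.17, 0.14 and 0.11 in clusters 3, 5 and 9, so shares could account for a part. For monocyte-like clusters the lowest median was -0.087 when these genes were left out of the clustering, with 0.41 and 0.87 in the others. In the main clustering, formed with these genes, medians were 0.06 in cluster 0 and 0.39 in cluster 4, beside 1.59 for the whole class. Cluster shares could thus account for much of the rise there. With 1 library per genotype, a difference between mice or libraries may also give the 1.413 and cannot be told apart from genotype.

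Some of the genes at least 2-fold different between the genotypes, in the same direction, with and without prey lay together on chromosome 1. Of 68 such genes 19 started between 63445891 and 91145089, among them Speg and B3gnt7, and none of 10000 random sets held as many within 30 Mb (highest 10). Only 15 of the 68 reached a mean of 5 CPM in a macrophage group. In macrophage-like tumour cells 22 of the 68 had at least 20 UMIs. Between Rubcn-/- and Rubcn+/- cells, 11 of these differed in the same direction as in bulk and 11 in the opposite one. Some of these directions rest on few UMIs, such as Camk2b with 14 in Rubcn+/- and 12 in Rubcn-/- cells. Counting error was not set against them, so the split does not decide whether the bulk differences recur. Reads shared between neighbours are argued against by the 13 loci left once genes within 100 kb were counted once. A stretch of DNA that differs between the WT and KO lines is a candidate explanation: 17.75% of the other genes of the stretch were called with the same sign in both states, against 7.44% elsewhere (Fisher's exact test, p = 1.05e-05; genes are not independent). Among 121 tested genes within 10 Mb of Rubcn, 0 were such genes, which is too few genes to set apart from the 68 of 18360. Of the 121, 34.71% were called between the genotypes without prey, against 28.36% of all tested genes.

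Splits of the libraries were counted to see whether chance can be excluded; except for the interaction, each was fitted on the compared groups alone, so the real counts differ from those over all 16 macrophage libraries. For WT_AT against WT_NS, the real split gave 11974 genes in 1 of 35 splits and the highest other 0, for KO_AT against KO_NS 12547 (1 of 35, highest other 0), for KO_NS against WT_NS 5830 (1 of 35, highest other 0), for KO_AT against WT_AT 2180 (1 of 35, highest other 4) and for AT_only against WT_NS 16544 (1 of 35, highest other 0). The true grouping thus gave the most genes in each. Every other split mixes the compared groups, which widens the spread within groups and lowers its count. These splits therefore cannot exclude chance differences between cultures or animals. For the interaction 3 of 100 splits gave at least the real 2004 genes, the highest other 3861. The 2 splits that gave more had all 4 KO_NS libraries right and only 1 of the 4 KO_AT libraries. Such a split puts the unfed genotype difference into the contrast, so its count gives no chance level for the interaction. For list counts the splits cannot decide: as many lists came in 5 of 35 splits for fed WT (real 11, highest other 14), 5 of 35 for fed KO (real 11, highest other 12), 7 of 35 for unfed genotypes (real 8, highest other 13), 4 of 35 for fed genotypes (real 9, highest other 10) and 5 of 100 for the interaction (real 11, highest other 12). Many of these splits exchange 1 library between the groups and so keep a part of the true difference. For fed KO, splits that exchange 2 libraries gave at most 3 lists. For unfed and fed genotypes such splits gave up to 8 and 9.

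Of 136 groups of 4 values, 17 held a library far from the others relative to the range of the group, where chance flags about 1 in 20. Small differences are thus flagged where the other libraries lie close together. Ccnd1 ran from 387.3 to 389.8 CPM in the other WT_NS libraries and Gdf3 from 23.65 to 23.82 in the other KO_NS libraries. Serpinb2 ran from 11.97 to 12.84 CPM in the other WT_AT libraries, a wider gap. The prey share of WT_AT replicate 2 was 2.673%. In CPM, Aldh1l2 was at 1.838 in KO_AT replicate 2 and at 7.211 in WT_NS replicate 4, Fbln2 at 34.09 and 16.55 in the same libraries, Fkbp9 at 10.52 and Thbs1 at 105.3 in WT_NS replicate 4, and Dmpk at 7.754 in KO_AT replicate 2. Ccnd1 was at 409.8 and Lrmda at 8.982 in WT_NS replicate 1, Gdf3 at 22.61 and Tox2 at 13.73 in KO_NS replicate 1, and Rhoj at 1.384 in KO_NS replicate 2. Marco was at 9.519 in KO_AT replicate 4, Serpinb2 at 18.04 in WT_AT replicate 4, and Speg at 28.98 and Vcan at 302.3 in WT_AT replicate 3.

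Feeding effects differed between the genotypes, KO minus WT on the log2 scale, for Cx3cr1 at 1.804, Tmeff1 at 1.673, Serpinb2 at 1.381, Egln3 at 1.334, Aldh1l2 at 1.298, Fbln2 at 1.084, Ccl2 at -1.69, Ccl7 at -1.647, Mcemp1 at -1.481, Ms4a4a at -1.394, Adgre4 at -1.341, Ciita at -1.124 and Rubcn at 0.158. List medians of that difference were -0.131 for type I interferon, -0.148 for interferon-gamma and MHC, -0.038 for pro-inflammatory, 0.054 for cholesterol, -0.053 for lysosome, -0.063 for nucleic acid sensing and for macrophage markers, 0.09 for oxidative stress, 0.204 for glycolysis and hypoxia, -0.088 for cell cycle and 0.26 for stromal genes.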

How the results depend on the processing

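Settings with the top 5% of doublet scores removed, with clustering without interferon and MHC genes, and with a mitochondrial limit of 5% for list ratios were chosen after seeing the data. Of 98 alternatives for gene counts 91 stayed within 1.5 times. Of 2710 for named genes 2694 kept their direction and side of the threshold and 16 lost the call, 15 of them with a library left out. Of 1596 for bulk lists 1482 kept theirs. Without genes higher in AT_only, 4 list tests turned from down to up and lost the call: the stress response for unfed (adjusted p = 0.44) and fed genotypes (0.668), neutrophil markers for fed genotypes (0.62) and cell cycle for the interaction (0.424). These tests used shorter lists, without 13 of 28 stress response genes, 9 of 15 neutrophil markers and 36 of 40 cell cycle genes. The cause was not tested unless stated.

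A minimum log2 fold change of 1 left 3225 genes (fed WT), 3074 (fed KO), 276 (unfed genotypes), 135 (fed genotypes) and 105 (interaction), and leaving out genes higher in AT_only left 7364 and 7327 for fed WT and KO. Lists passing with an estimated correlation were 5, 4, 0, 1 and 0, with fry 22, 18, 12, 10 and 8, and without genes higher in AT_only 3 for fed genotypes and 7 for the interaction.

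Prey shares from the 100 genes with the highest ratio were 2.31% in WT_AT and 2.27% in KO_AT, and on total counts 2.42% and 2.31%. Leaving out AT_only libraries gave 3.04% to 3.15% in KO_AT, and leaving out WT_AT replicate 2 a difference of -0.30 (exact permutation p = 0.0286), with differences from -0.3044 to -0.0449 over all libraries left out.

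Macrophage-like shares in Rubcn+/- were 57.6% at resolution 0.5, 58.8% at 5% mitochondrial UMIs, 60.6% with top scores removed and 57.3% without interferon genes in the clustering; in Rubcn-/- they were 39.1% with doublets kept, 49.7% at resolution 0.5, 48.3% at 5% and 58.9% with top scores removed. Monocyte-like shares in Rubcn+/- were 22.9% at 5% mitochondrial UMIs, 22.9% with top scores removed and 21.3% without interferon genes, and in Rubcn-/- 38.7% with doublets kept and 25.2% with top scores removed. Keeping doublets returned only 5 Rubcn-/- cells. Macrophage-like cells of that library nevertheless went from 689 to 624 and monocyte-like cells from 563 to 618. The 5 cells cannot make up that shift, so it shows how far the shares depend on the clustering. The interferon median in macrophage-like cells was 0.32 with doublets kept, 0.60 with top scores removed and 0.30 without interferon genes in the clustering, and in monocyte-like cells 1.503 without mitochondrial and ribosomal genes and 1.81 with top scores removed. Among the single cells, reversed were glycolysis in macrophage-like cells, at 0.067 (resolution 0.5), 0.006 (5% mitochondrial UMIs) and 0.005 (top scores removed), glycolysis in monocyte-like cells, at 0.023 (without interferon genes), and dendritic cell markers in monocyte-like cells, at -0.247 (5% mitochondrial UMIs), -0.443 (top scores removed) and -0.026 (without interferon genes). A minimum of 2000 UMIs removed no cell.

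Replicate numbers were not taken to pair the samples: over 24 comparisons of libraries with the same number r ran from -0.264 to 0.236, 6 were over 0.1 and 10 were the best for that library; between WT_AT and KO_AT, r was 0.012, 0.174, 0.133 and 0.236. With a replicate block, 12576, 12565, 5133, 2572, 1907 and 15750 genes were called in the order of the contrasts, and 2 list calls changed: LXR and PPAR targets passed for fed KO (adjusted p = 0.0471) and macrophage markers no longer passed for fed genotypes (0.0516). Fry ended 5 calls, type I interferon for fed genotypes (0.248) and type I interferon (0.21), lysosome (0.179), cell cycle (0.326) and stromal markers (0.282) for the interaction. In the simulation, 1.1-fold changes in genes above the median level were recovered at 12% to 58%, which limits what this depth and spread can show. Changes in genes below that level were not simulated.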

Other observations

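The lists used here were fixed before the data were examined, but the dendritic cell 2-like class was taken up after the results were seen. With 1 library per genotype no test applies. In dendritic cell 2-like tumour cells, 22 of 22 cholesterol biosynthesis genes were lower in the Rubcn-/- library, with a median log2 ratio of -0.47, and 29 of 36 interferon-gamma and MHC genes were lower, with a median of -0.29. Cell cycle genes were higher in 13 of 15, with a median of 0.93, and glycolysis and hypoxia genes in 22 of 25, with a median of 0.29; glycolysis medians were -0.08 in macrophage-like and -0.16 in monocyte-like cells, where they changed sign under other settings. Nucleic acid sensing genes had a median of -0.30 and monocyte markers of -0.29. These values are from the main clustering only. In this class the type I interferon median went from -0.08 to 0.70 when interferon and MHC genes were left out of the clustering. The direction of other lists may likewise depend on which cells the class holds. The largest falls were in transcripts of other cell types, Gzma at 63 and 1 UMIs and Krt15 at 52 and 1 in Rubcn+/- and Rubcn-/-, so the lists are not shown to have changed within one kind of cell. Retnla was at 166.9 CPM in Rubcn-/- and 7.32 in Rubcn+/- cells, and the transcription factor gene Cebpb at 157.7 and 27.1. The interferon chemokine Cxcl9 was at 5.56 and 139.1 CPM, and Ccl24 at 28.4 and 330.1.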
